A study of Mus musculus with 9 samples.

How the data were processed

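Granulosa cells, the somatic cells that surround and nourish the oocyte, were isolated from the ovaries of female C57BL/6 mice and profiled by RNA sequencing of polyadenylated RNA, per the labels' protocols. The labels give 3 groups of 3 libraries: Control, cyclophosphamide alone (CTX) and cyclophosphamide with hydroxychloroquine (CTX_HCQ). Per the series' design text, cyclophosphamide was injected at 120 mg per kg, and hydroxychloroquine was given by mouth at 40 mg per kg per day from 7 days before the injection to 4 weeks after it. The control is described as vehicle in the design text and as untreated in the labels, and no choice between the 2 was made here. The labels do not say whether a library came from 1 mouse or from a pool, so p-values measure only the spread between these libraries, which may in part be technical.

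The authors deposited 1 table of FPKM, expression scaled to gene length and library size, for the 9 libraries. Per the submitters' processing notes, the tools were fastp 0.23.2, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, and the genome build was GRCm39, also named mm39. The notes give the tools without their roles or settings, and strandedness is not given in the sources used here. Reads of overlapping or antisense genes can therefore not be told apart. Near-identical copies, such as Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Hspa1a and Hspa1b, and the immunoglobulin segments, are uncertain as single genes. The reference at hand was an annotation of another build (GENCODE M21), so it gave gene symbols and exon lengths, and no coordinates are printed. Of the 56748 Ensembl identifiers in the table, 52073 matched a symbol, and 14144 of the 14431 tested genes did.

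Depth was recovered from the deposited FPKM. With the summed exon length of each gene, low values fell on whole reads, and whole reads within a tolerance of 0.02 reads were obtained for 14431 of 14431 tested genes. For 13573 of them the annotation's own length served, and for 858 the length was searched for. Recovered totals ran from 13922195 reads in CTX_HCQ 3 to 17768358 reads in Control 2. The library sizes behind the FPKM differ from these totals, with a recovered total of 0.9073 times that size in CTX_HCQ 3. On simulated reads the recovery returned the true count for 99.99% of the genes it resolved.

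Genes with an FPKM of at least 1 in at least 3 of the 9 libraries were tested. Values were analysed as log2(FPKM + 1), so a log2 fold change understates the change of genes with low FPKM. All 9 libraries entered 1 linear model with a mean per group in limma 3.58.1 (R 4.3.3), with moderated variances that follow a trend on mean expression, and p-values were adjusted by the Benjamini-Hochberg method in each of 3 comparisons, with a threshold of 0.05. Gene lists, 29 in number, were tested with limma's camera at its preset inter-gene correlation of 0.01, with adjustment over the 87 tests of all lists and comparisons. A list needed at least 5 tested members. Camera with an estimated correlation and limma's fry were run as alternatives.

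Genes named in the text followed a rule written before the data were examined, except Ovgp1, Foxj1, Cyp17a1, Ptgs2 and Pgr, which were chosen after their values had been seen. Where genes passed, the 10 largest rises and falls without overlap between groups would have been named. Since none passed in any comparison, the 5 genes per direction with the smallest p are given as values. Names made of Gm and digits, or ending in Rik, were left out. Cgas, Sting1, Tbk1, Irf3, Cdkn1a, Cdkn2a, Trp53, Glb1, Lmnb1, Tfam, Amh, Fshr, Foxl2 and Cyp19a1 are given in every comparison, and each called list is described with up to 4 members of smallest p. Some members of the lysosome list that this rule names are not reported here. Opposition between comparisons was measured as the correlation across genes of the log2 fold changes, beside values simulated for unchanged groups by 10000 random rotations of the residuals.

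The tests were tried on simulated data for the comparison of CTX with Control. With rotated residuals of the real libraries over 14431 genes, limma recovered 38.6% of genes changed by a log2 of 1 and 86.1% of genes changed by a log2 of 2. Camera at the preset correlation called a median of 7 of 29 lists between unchanged groups in 100 draws, with a 95th percentile of 11 and a maximum of 14. With the estimated correlation it called 0. The preset test therefore makes calls here without any group effect.

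Replicates were compared before averaging. Within groups, the chi-square of the recovered reads per degree of freedom lay between 15.6 and 164, so no 2 libraries differed by as little as sampling noise. Alternatives covered the pseudocount, the filter, the scaling between libraries, library weights, the samples in the fit, the replicate number as a block, limma voom on recovered reads, and each library left out. A further 4 alternatives were added after the data had been seen: scaling to recovered totals, removal of a gene length trend, omission of CTX 3 with CTX_HCQ 3, and the ovulation list as a covariate.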

Results

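Transcript levels were measured in granulosa cells of 9 libraries, 3 per group, to describe ovaries damaged by cyclophosphamide, an alkylating drug used here to model premature ovarian failure, with and without hydroxychloroquine, a drug that accumulates in lysosomes. The title of the study names granulosa cell senescence and the sensing of mitochondrial DNA by cGAS as its subject. Depth was 13922195 to 17768358 recovered reads per library, and 14431 genes were tested. Values are mean FPKM ± SD with n = 3 libraries per group, and log2 fold changes are on the log2(FPKM + 1) scale with their standard error (SE).

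The libraries did not separate by group. The mean correlation across tested genes was 0.941 over the 9 pairs within groups and 0.936 over the 27 pairs between groups, and for 3 of the 9 libraries the closest library belonged to the same group. CTX_HCQ 1 correlated at 0.981 with Control 2, and Control 1 at 0.975 with CTX 2. CTX_HCQ 2 and CTX_HCQ 3 correlated at 0.881. Mitochondrial transcripts made up 28.9% of FPKM in CTX 3 and 11.7% to 17.5% in the other 8 libraries. Ovgp1, which encodes the oviduct-specific glycoprotein, stood at 339 FPKM in CTX 3, 91 in CTX 1, 44.4 in CTX 2 and 55.5 in Control 1, and at 11.3 or less in the remaining 5 libraries.

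**Figure D1:**
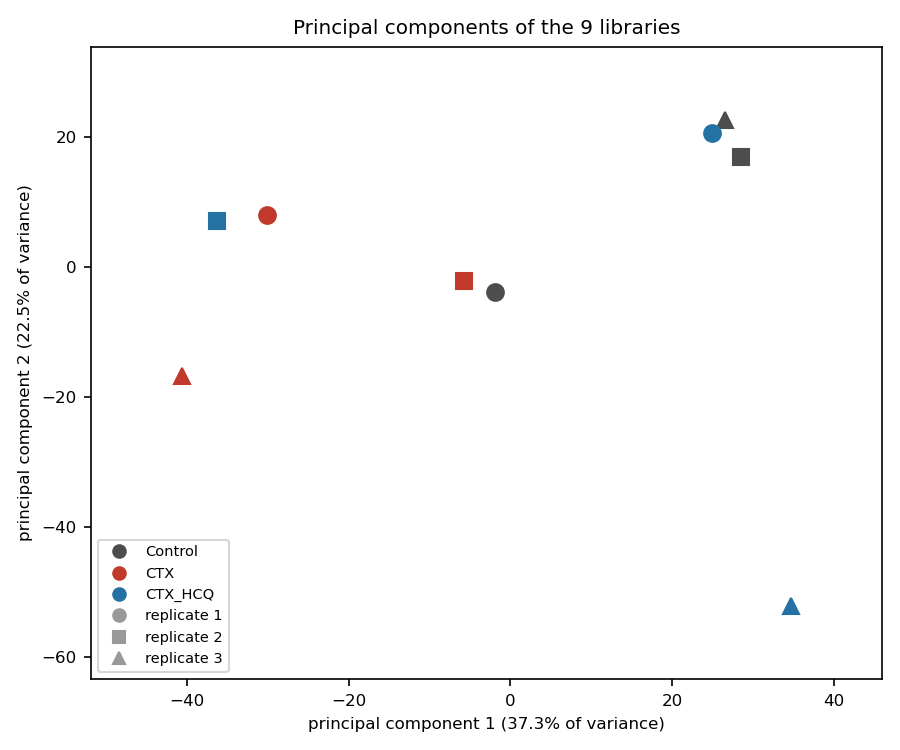
Position of the 9 libraries on the first 2 principal components of log2(FPKM + 1) over the tested genes, with 37.3% and 22.5% of the variance, coloured by group and with a symbol per replicate number. CTX_HCQ 1 lies beside Control 2 and Control 3, Control 1 lies beside CTX 2, and CTX_HCQ 3 stands apart on component 2.

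The first comparison, CTX with Control, addressed the effect of cyclophosphamide. The gene with the smallest p was Cish (ENSMUSG00000032578), an inhibitor of cytokine signalling, at 15.4 ± 5.14 FPKM in CTX and 4.02 ± 0.692 in Control, a log2 difference of 1.66 (SE 0.32). Socs1 (ENSMUSG00000038037), of the same family, stood at 9.69 ± 4.2 and 2.56 ± 1.09, a difference of 1.54 (SE 0.34). Rsph9, a component of the radial spokes of motile cilia, stood at 5.71 ± 0.705 in CTX and 2.36 ± 1.06 in Control. Ankrd66 at 1.69 ± 0.14 and 0.24 ± 0.3, and Mir3092 at 11.6 ± 8.07 and 0.409 ± 0.709, completed the higher genes and rested on at most 39 and 32 reads per library. On the lower side stood Crispld2 at 34.2 ± 4.74 in CTX and 69.5 ± 10.5 in Control, Emilin2 at 5.48 ± 0.857 and 9.48 ± 0.149, Fgd3 at 2.15 ± 0.26 and 9.84 ± 5.16, the collagen hydroxylase gene P3h2 at 2.16 ± 0.666 and 5.55 ± 0.822, and the immunoglobulin segment Ighv8-8 at 0.111 ± 0.0966 and 1.91 ± 1.06, the last on at most 19 reads. None of these genes passed: limma called 0 of 14431 genes, with a smallest adjusted p of 0.639, and voom on the recovered reads called 0. Library weights gave 648 calls, where other splits of the same 6 libraries gave up to 2068, and 13 genes were called without Control 1. At an unadjusted p under 0.05 there were 1126 genes with limma and 1141 with voom. The limma count was 424 without Control 2, 468 without Control 3, 678 without CTX 1, 681 without CTX 3, 1693 without CTX_HCQ 2 and 329 with the ovulation list as covariate. It was 2067 with only the 2 groups in the fit, 3935 with library weights, 1906 with no filter on low values and 580 with a mean FPKM of at least 5. The values of CTX and Control did not overlap in 2842 genes, 19.7% of those tested, where chance gives 10%. This 10% is an average over all splits of the 6 libraries. Genes vary together, so a single split can lie far from it, and the share was not counted for other splits.

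Of the genes chosen in advance, none passed in this comparison (adjusted p by limma between 0.639 and 0.984 for the 13 tested). Cdkn1a, which encodes the cell cycle inhibitor p21, stood at 6.23 ± 1.06 FPKM in CTX and 26.1 ± 17.3 in Control, a log2 difference of -1.61 (SE 0.65). The Control libraries held 7.05, 30.4 and 40.7. Amh, the anti-Müllerian hormone gene of growing follicles, stood at 268 ± 137 in CTX and 421 ± 104 in Control, and Fshr, the receptor of follicle-stimulating hormone, at 25.2 ± 7.5 and 33.7 ± 10.5. Foxl2, a granulosa cell transcription factor, stood at 75.6 ± 9.87 and 83.3 ± 9.93, and the aromatase gene Cyp19a1 at 21.9 ± 14.9 and 8.53 ± 3.06. Glb1, which encodes the beta-galactosidase stained as a senescence marker, stood at 26.6 ± 2.55 in CTX and 36.3 ± 4.2 in Control. The nuclear lamina gene Lmnb1 stood at 33.5 ± 7.29 and 39.1 ± 4.49, and Trp53 at 26.1 ± 7.69 and 30.2 ± 7.28. In the DNA-sensing pathway, Cgas stood at 1.12 ± 0.168 in CTX and 0.99 ± 0.573 in Control, Sting1 at 4.55 ± 1.34 and 3.59 ± 0.304, Tbk1 at 8.6 ± 1.01 and 7.62 ± 1.33, and Irf3 at 25.2 ± 5.15 and 24.9 ± 4.65. Tfam, which packages mitochondrial DNA, stood at 13.1 ± 2.84 and 11.4 ± 0.672. Cdkn2a lay below the filter in all groups and was not tested, with 0.783 ± 0.194 FPKM in CTX, 0.42 ± 0.428 in Control and 0.282 ± 0.349 in CTX_HCQ from 1 to 19 reads per library.

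**Figure D2:**
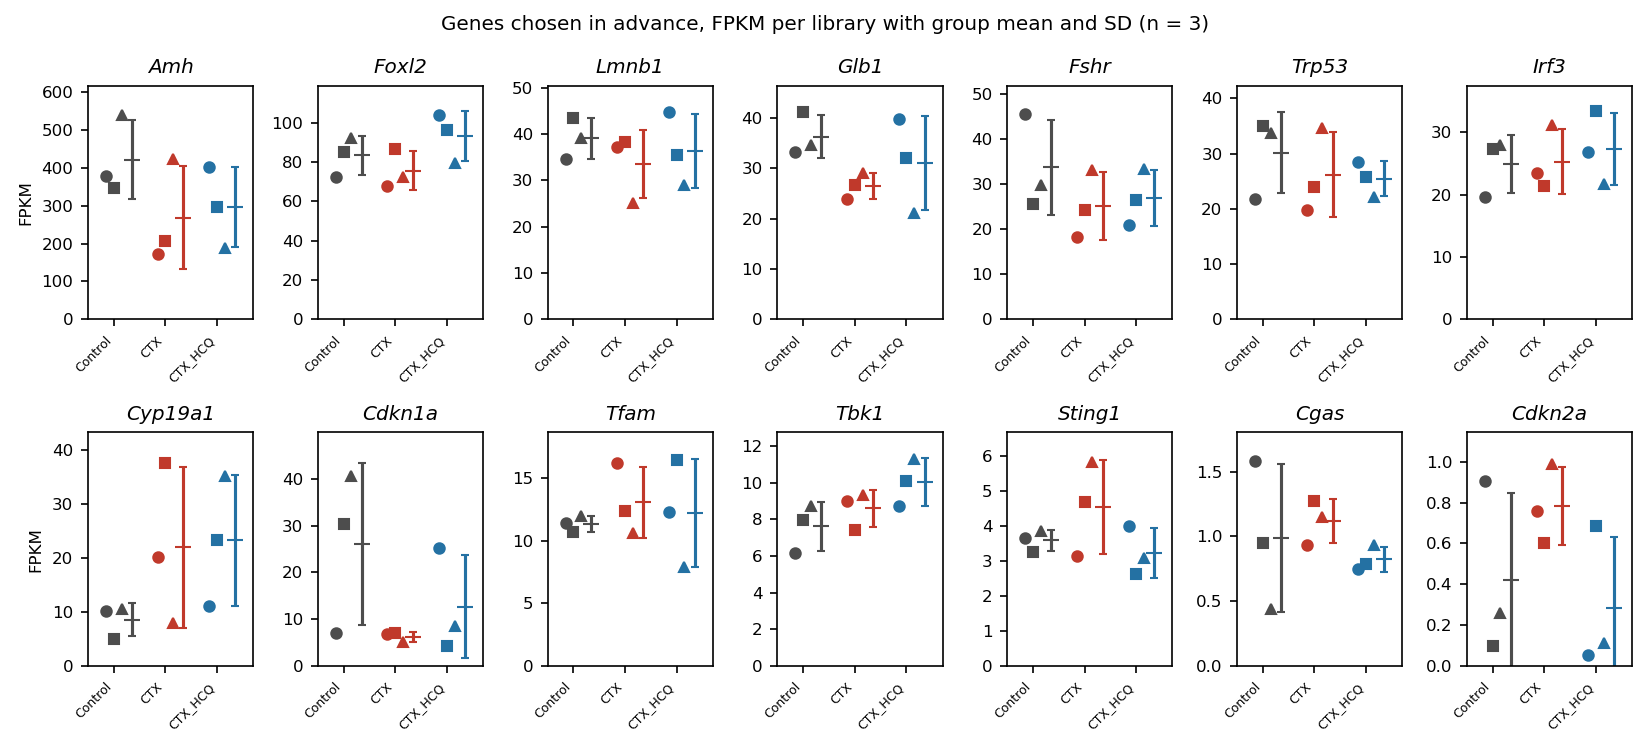
FPKM of the 14 genes chosen in advance in each of the 9 libraries, with the group mean and SD (n = 3) at the right of each group and each vertical axis starting at 0. Cdkn1a reached 30.4 and 40.7 in 2 Control libraries and 25.1 in CTX_HCQ 1, none of the 13 tested genes passed in any comparison, and the lower SD bars of Cdkn2a, which was not tested, end at the axis.

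At the preset correlation, camera called 12 of 29 gene lists between CTX and Control. Interferon-stimulated genes, which respond to antiviral signalling, were higher in CTX in 22 of 26 measured members, with a median log2 difference of 0.34 (0.22 without Control 1), an adjusted p of 7.11e-06 and an adjusted p of 0.823 with an estimated correlation. Isg15 stood at 10.7 ± 4.74 FPKM in CTX and 3.46 ± 0.684 in Control, Ifit1 at 4.42 ± 1.49 and 1.6 ± 0.262, Ifit3 at 6.02 ± 2.32 and 2.56 ± 0.312, and Gbp3 at 7.94 ± 1.88 and 3.8 ± 1.05. In this list 4 genes passed when adjusted over the list alone and 0 over all genes. Cholesterol synthesis genes were higher in 20 of 24 members (median 0.64, adjusted p 2.39e-05, estimated-correlation adjusted p 0.843, median 0.365 without CTX 1), among them Nsdhl at 26 ± 2.43 in CTX and 14.7 ± 7.05 in Control, Tm7sf2 at 13.8 ± 4.32 and 6.39 ± 2.67, and Pmvk at 19.1 ± 5.02 and 9.46 ± 2.38. By library median on this list, Control 1 at 0.39 lay above CTX 3 at -0.02, while Control 2 and Control 3 stood at -0.51 and -0.37. All 13 mitochondrially encoded genes were higher (median 0.77, adjusted p 6.11e-05, estimated-correlation adjusted p 0.823, median 0.369 without CTX 3), with mt-Co2 at 818 ± 698 in CTX and 265 ± 98.7 in Control and mt-Atp6 at 922 ± 845 and 181 ± 46.7. In CTX 3 mt-Co2 held 1622 FPKM and in the other CTX libraries 460 and 373. Nuclear genes of oxidative phosphorylation were higher in 38 of 42 members (median 0.34, adjusted p 9.36e-05, estimated-correlation adjusted p 0.843), for example Uqcrq at 83.1 ± 16.6 and 47.1 ± 9.04 and Ndufv2 at 62.8 ± 10.4 and 40.3 ± 4.12.

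Markers of endothelial cells were higher in CTX in 11 of 11 members (median 0.65, adjusted p 0.000919, estimated-correlation adjusted p 0.843, median 1.12 without Control 1 and 0.429 without Control 2, and from 0.115 to 1.12 over 18 alternatives), with Egfl7 at 7.7 ± 1.8 FPKM in CTX and 4.03 ± 2.01 in Control and Emcn at 3.28 ± 0.883 and 1.56 ± 1.42. Antioxidant and NRF2 genes were higher in 15 of 20 (median 0.28, adjusted p 0.0379, estimated-correlation adjusted p 0.843), with Gsta4 at 78.2 ± 2.02 and 37.8 ± 14.3 and Sod2 at 11.6 ± 1.5 and 7.89 ± 0.571. Immediate early and heat shock genes were higher in 15 of 22 (median 0.31, adjusted p 0.0379, estimated-correlation adjusted p 0.843, median 0.192 without CTX 1), led by the chaperone genes Hspa1a at 6.82 ± 0.84 and 2.56 ± 0.929 and Hspa1b at 17.1 ± 0.826 and 8.71 ± 4.66. Lower in CTX were 5 of 5 erythroid genes (median -1.44, adjusted p 0.00448, estimated-correlation adjusted p 0.823, median -0.558 without Control 3), with Hbb-bs at 181 ± 13.1 in CTX and 700 ± 688 in Control, of which Control 3 held 1490. Ovulation and cumulus genes, 14 in the list, were lower in 5 of 5 measured members (median -1.69, adjusted p 0.0113, estimated-correlation adjusted p 0.823, median -1.103 without Control 3), with Adamts1 at 11.8 ± 5.31 and 120 ± 91.8 and Runx1 at 4.08 ± 0.874 and 19.2 ± 12.6. Matrix and fibrosis genes were lower in 17 of 20 (median -0.30, adjusted p 0.00614, estimated-correlation adjusted p 0.823, median -0.175 without CTX 3), with Loxl2 at 12.6 ± 5.77 and 56.7 ± 36.9 and Col4a1 at 65.8 ± 22.1 and 131 ± 33.5. Targets of p53 were lower in 11 of 17 (median -0.32, adjusted p 0.0201, estimated-correlation adjusted p 0.823, median -0.506 without Control 1 and -0.126 without Control 3), with Zmat3 at 2.1 ± 0.546 and 4.62 ± 1.57 and Trp53inp1 at 15.5 ± 3.82 and 30.7 ± 11.2. Control 1 did not follow this difference. It stood at -0.2 on the p53 list, below the CTX libraries at -0.09, -0.18 and -0.09, with Control 2 and Control 3 at 0.26 and 0.41. Lysosome and autophagy genes were lower in 27 of 36 (median -0.18, adjusted p 0.0341, estimated-correlation adjusted p 0.843, median -0.106 without Control 1). With an estimated correlation none of the 12 lists was called, and fry called 0. Between unchanged groups simulated for this comparison the preset test called a median of 7 lists and at most 14. Some calls ended when 1 library was left out, with adjusted p from 0.0587 to 0.207. They were those of the lysosome, antioxidant, immediate early and matrix lists without Control 1, and of p53 targets without Control 3. Without CTX 1 the antioxidant and immediate early lists were not called. Without CTX 2 these 2 and the erythroid, p53 and lysosome lists were not called. The matrix list was not called without CTX 3, nor the immediate early list without CTX_HCQ 1 or CTX_HCQ 3. Without CTX 3 and CTX_HCQ 3 together, a choice made after the data had been seen, 8 of the 12 were still called. The ovulation, p53, lysosome and matrix lists were not, with adjusted p from 0.055 to 0.072, and the fibroblast and stroma list was called in addition (median -0.217, adjusted p 0.022). With a mean FPKM of at least 5 the p53, lysosome and immediate early lists were not called, and with quantile normalization or the length trend removed the antioxidant and immediate early lists were not. With the ovulation list as covariate the ovulation, endothelial, p53 and lysosome lists were not called. Adjusted p in these settings ran from 0.0501 to 0.735. Lists were also gained: fibroblasts and stroma with the covariate, without Control 2 and without CTX_HCQ 3, adipocytes with the covariate, smooth muscle without Control 1, lymphocytes without Control 3 and with the length trend removed, and macrophages without CTX 1. With the covariate 10 lists were called, 8 of the 12 and these 2.

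The second comparison, CTX_HCQ with CTX, addressed the effect of hydroxychloroquine in mice given cyclophosphamide. The smallest p belonged to Rsph1 (ENSMUSG00000024033), a radial spoke gene of motile cilia, at 2.08 ± 0.694 FPKM in CTX_HCQ and 7.96 ± 2.22 in CTX, a log2 difference of -1.54 (SE 0.26). Fam92b stood at 0.09 ± 0.0781 and 2.23 ± 0.768, Ankrd66 at 0.127 ± 0.117 and 1.69 ± 0.14, the dynein light chain gene Dynlt1b at 15.4 ± 2.13 and 32.8 ± 4.32, and Ndufb4c at 1.52 ± 0.281 and 4.09 ± 0.898. Ovgp1 stood at 11.3 FPKM or less in the CTX_HCQ libraries and at 44.4 or more in the CTX libraries. The genes higher in CTX_HCQ were mostly short noncoding genes with few reads: Mir7087 at 7.92 ± 4.52 and 0.58 ± 1, Snord55 at 24.7 ± 10.5 and 8.36 ± 4.17, and Rnu73b at 23.1 ± 7.16 and 8.42 ± 1.56, none above 50 reads. Snord37 was listed at 0 in all CTX libraries and at 3.71 ± 2.41 in CTX_HCQ, from at most 6 reads. An identifier that carries the symbol Rpl24 stood at 4 ± 0.45 and 1.73 ± 0.593. Limma called 0 genes, with a smallest adjusted p of 0.394, 785 genes at an unadjusted p under 0.05, and 748 with voom, which also called 0. Without CTX_HCQ 2 the count at an unadjusted p under 0.05 was 2440 and without CTX 1 it was 483. It was 2832 with library weights, 1713 with no filter and 370 with a mean FPKM of at least 5. As to calls, 10 genes were called without Control 1, and 1 gene with library weights. Values did not overlap in 1158 genes, 8.02%, where chance gives 10%.

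None of the genes chosen in advance passed (adjusted p by limma between 0.906 and 0.997). Sting1 stood at 3.23 ± 0.712 FPKM in CTX_HCQ and 4.55 ± 1.34 in CTX, Cgas at 0.823 ± 0.0973 and 1.12 ± 0.168, Tbk1 at 10 ± 1.27 and 8.6 ± 1.01, and Irf3 at 27.3 ± 5.79 and 25.2 ± 5.15. Cdkn1a stood at 12.6 ± 11 in CTX_HCQ, where CTX_HCQ 1 held 25.1 and the other libraries 4.28 and 8.53. Glb1 stood at 31 ± 9.29, Lmnb1 at 36.4 ± 7.98, Trp53 at 25.5 ± 3.16 and Tfam at 12.3 ± 4.29. Amh stood at 296 ± 107, Fshr at 27 ± 6.28, Foxl2 at 93.1 ± 12.5 and Cyp19a1 at 23.2 ± 12.

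Camera called 5 lists at the preset correlation, each lower in CTX_HCQ than in CTX. Cholesterol synthesis genes were lower in 24 of 24 members (median -0.71, adjusted p 2.27e-10, estimated-correlation adjusted p 0.823, median -0.454 without CTX 1 and -1.097 without CTX 3), with Nsdhl at 11.7 ± 2.31 FPKM in CTX_HCQ and 26 ± 2.43 in CTX, Sqle, which makes the epoxide of squalene, at 24.8 ± 7.25 and 49 ± 15.1, and Lss at 7.09 ± 3.46 and 14.9 ± 5.13. The groups overlapped on this list, with CTX libraries at 0.88, 0.56 and -0.02 and CTX_HCQ libraries at -0.41, 0.17 and -0.67. Nuclear genes of oxidative phosphorylation were lower in 42 of 42 (median -0.35, adjusted p 1.02e-06, estimated-correlation adjusted p 0.843, median -0.699 without CTX_HCQ 2 and -0.204 with the length trend removed), with Uqcrq at 40.4 ± 21 and 83.1 ± 16.6 and Cox8a at 196 ± 74.5 and 362 ± 76.3. Without CTX_HCQ 3 the median of this list was 0.04 (adjusted p 0.757). CTX_HCQ 3 stood at -0.93 on it and the other CTX_HCQ libraries at -0.02 and 0.5. All 13 mitochondrially encoded genes were lower (median -0.98, adjusted p 1.88e-06, estimated-correlation adjusted p 0.823, median -0.579 without CTX 3 and -0.402 with quantile normalization), with mt-Co2 at 198 ± 79.5 and 818 ± 698. CTX 3 stood at 1.4 on this list and the other CTX libraries at 0.37 and -0.04. Antioxidant and NRF2 genes were lower in 19 of 20 (median -0.42, adjusted p 0.00032, estimated-correlation adjusted p 0.823, median -0.262 with quantile normalization and -0.278 with the length trend removed), with the peroxidase gene Gpx3 at 382 ± 159 and 755 ± 309 and the catalase gene Cat at 29.8 ± 5.37 and 40.3 ± 2.83. Without CTX_HCQ 3 this list was not called, with a median of -0.16 (adjusted p 0.158). Interferon-stimulated genes were lower in 24 of 26 (median -0.21, adjusted p 0.00044, estimated-correlation adjusted p 0.823), with Ifi27l2a at 22.5 ± 5.1 and 34.7 ± 7.94 and Ifit1 at 2.66 ± 1.06 and 4.42 ± 1.49. Without CTX 2 this list was not called, with a median of -0.135 (adjusted p 0.0781). With an estimated correlation none of the 5 was called, and fry called 0. Without CTX 3 and CTX_HCQ 3 together 3 of the 5 were still called, the mitochondrially encoded list with a median of -0.55 (adjusted p 2.81e-05). The antioxidant list at -0.184 (adjusted p 0.072) and the nuclear oxidative phosphorylation list at -0.003 (adjusted p 0.737) were not. The fibroblast and stroma list was called in addition, higher in CTX_HCQ (median 0.49, adjusted p 0.000224). With 1 library left out, 5 lists were gained without CTX_HCQ 2, 4 without CTX 1 and 3 without CTX 3.

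**Figure D3:**
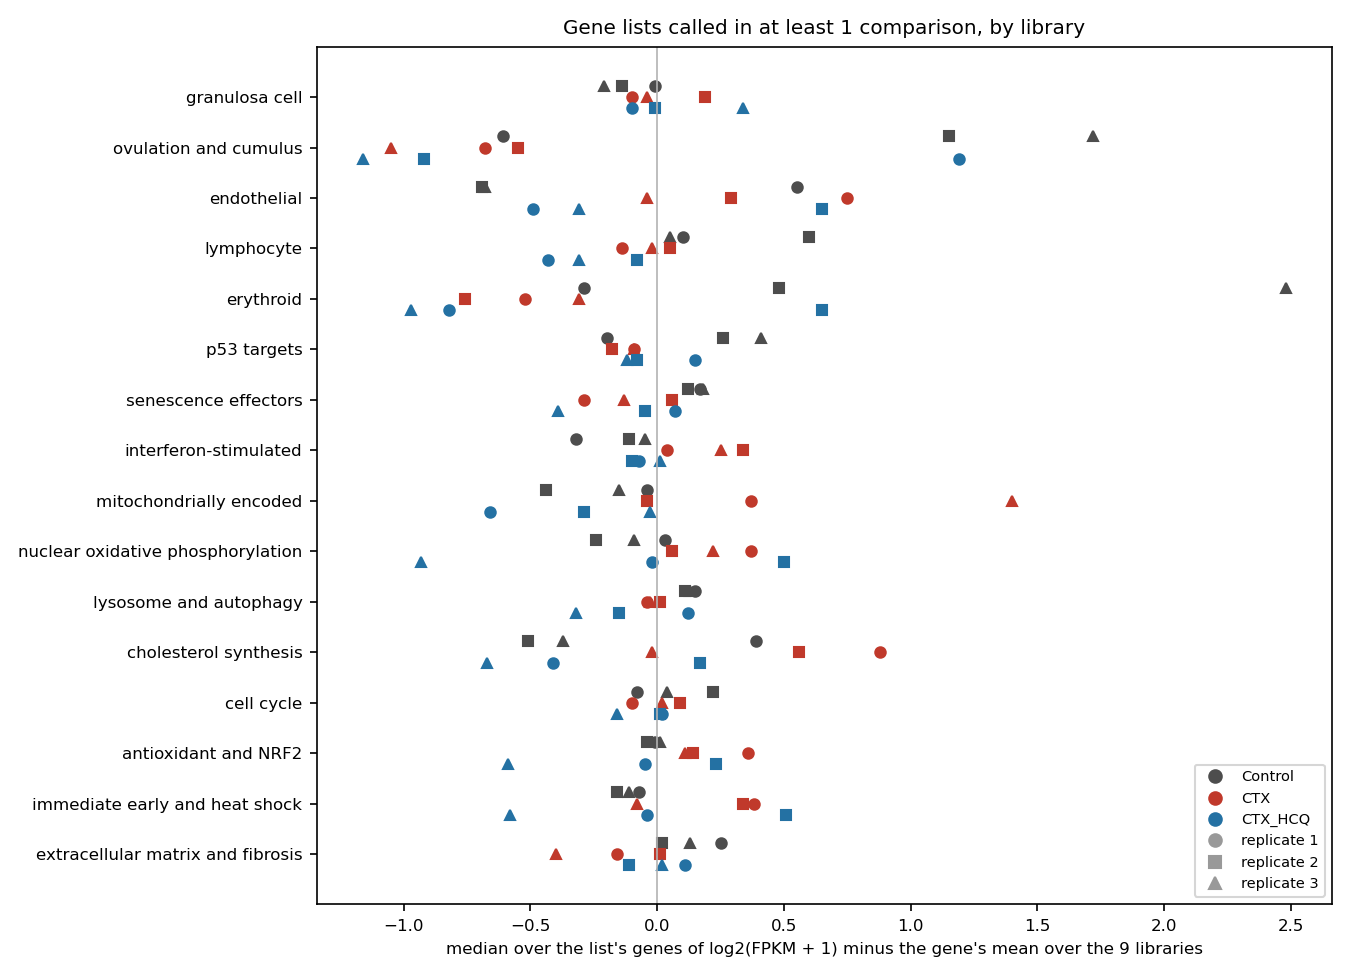
Median over each list's genes of log2(FPKM + 1) minus the gene's mean over the 9 libraries, 1 point per library, for the lists called in at least 1 comparison at the preset correlation. The ovulation list reached 1.15 and 1.72 in Control 2 and Control 3 and 1.19 in CTX_HCQ 1, and the nuclear oxidative phosphorylation list stood at -0.93 in CTX_HCQ 3.

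The third comparison, CTX_HCQ with Control, addressed what differed under both drugs. Igha (ENSMUSG00000095079), the heavy chain gene of immunoglobulin A, had the smallest p, at 24.5 ± 4.8 FPKM in CTX_HCQ and 4.11 ± 1.7 in Control, a log2 difference of 2.36 (SE 0.35), from 110 to 1189 reads per library. Jchain, which encodes the immunoglobulin joining chain and is not particular to immunoglobulin A, stood at 3.73 ± 1.45 and 0.891 ± 0.487. The retinol carrier gene Rbp4 stood at 4.39 ± 1.2 and 1.81 ± 0.67. Chchd2-ps at 2.22 ± 0.342 and 0.498 ± 0.308 and Snora15 at 2.38 ± 1.41 and 0.296 ± 0.257 rested on at most 19 and 8 reads. On the lower side stood the chemokine gene Ccl5 at 1.62 ± 0.561 and 4.39 ± 0.939, the cytotoxic granule gene Gzma at 0.939 ± 0.443 and 2.79 ± 0.436, Cd34 at 6.77 ± 1.35 and 13.6 ± 1.19, Dynlt1b at 15.4 ± 2.13 and 25.1 ± 2.31, and Rab7-ps1 at 4.03 ± 1.38 and 7.66 ± 0.237. Limma called 0 genes, with a smallest adjusted p of 0.669 and 312 genes at an unadjusted p under 0.05, and voom called 0, with 308. This count was 1079 without CTX_HCQ 1, 480 without Control 1, 157 without Control 2, 193 without Control 3, 560 without CTX 3 and CTX_HCQ 3 together and 200 with the ovulation list as covariate. It was 905 with library weights, 926 with no filter and 146 with a mean FPKM of at least 5. Library weights gave 1 call. Values did not overlap in 911 genes, 6.31%, where chance gives 10%. Among the genes chosen in advance, Cyp19a1 differed by 1.26 (SE 0.54), Cdkn1a by -1 (SE 0.65), Amh by -0.55 (SE 0.41) and Tbk1 by 0.36 (SE 0.18). Fshr differed by -0.29 (SE 0.29), Glb1 by -0.26 (SE 0.24), Trp53 by -0.21 (SE 0.26), Foxl2 by 0.16 (SE 0.21), Sting1 by -0.13 (SE 0.21), Lmnb1 by -0.12 (SE 0.23), Irf3 by 0.12 (SE 0.23), Cgas by -0.09 (SE 0.24) and Tfam by 0.05 (SE 0.25). None of the 13 tested passed, with an adjusted p of 1 by limma for each.

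Camera called 9 lists at the preset correlation in this comparison. Lysosome and autophagy genes were lower in CTX_HCQ in 33 of 36 members (median -0.27, adjusted p 7.11e-06, estimated-correlation adjusted p 0.823, median -0.417 without CTX_HCQ 1 and -0.167 without CTX_HCQ 3), with Neu1 at 13.8 ± 2.1 FPKM in CTX_HCQ and 17.9 ± 1.71 in Control. Erythroid genes were lower in 5 of 5 (median -1.29, adjusted p 0.000156, estimated-correlation adjusted p 0.823, median -0.538 without Control 3), with Alas2 at 3.55 ± 0.39 and 14.2 ± 13.4. Lymphocyte markers, 12 in the list, were lower in 5 of 5 measured members (median -0.48, adjusted p 0.00232, estimated-correlation adjusted p 0.823, median -0.22 and not called without Control 2), with Trbc2 at 1.99 ± 1.29 and 4.72 ± 2.03 and Lck at 1.24 ± 0.319 and 2.26 ± 0.786. These 2 genes rested on 9 to 85 and 46 to 165 reads per library. Ovulation and cumulus genes were lower in 5 of 5 (median -0.97, adjusted p 0.0257, estimated-correlation adjusted p 0.843, median -0.637 without Control 2, -0.56 without Control 3, -0.49 without CTX_HCQ 2 and -0.581 without CTX_HCQ 3), with Runx2 at 12.5 ± 6.68 and 23.4 ± 4.07. Targets of p53 were lower in 14 of 17 (median -0.18, adjusted p 0.0348, estimated-correlation adjusted p 0.823, median -0.29 without Control 1, -0.079 without Control 3 and -0.103 without CTX_HCQ 3), with Ccng1 at 18.8 ± 6.52 and 30.3 ± 10.5, and senescence effectors in 10 of 12 (median -0.20, adjusted p 0.0493, estimated-correlation adjusted p 0.823), with Hmga1 at 11 ± 3.6 and 17.2 ± 6.89. Both of these lists hold Cdkn1a. On the p53 list Control 1 stood at -0.2, below the CTX_HCQ libraries at 0.15, -0.08 and -0.12, and Control 2 and Control 3 at 0.26 and 0.41. Cell cycle genes were lower in 28 of 36 (median -0.12, adjusted p 0.0363, estimated-correlation adjusted p 0.843, median -0.046 without Control 2), with Nusap1 at 6.06 ± 1.06 and 8.83 ± 0.57, while Cenpe stood higher, at 4.86 ± 1.79 and 2.91 ± 0.572. Granulosa cell markers were higher in 14 of 18 (median 0.13, adjusted p 0.032, estimated-correlation adjusted p 0.823, median 0.263 without Control 1 and 0.221 without CTX_HCQ 1), with Ihh at 90.2 ± 40.6 and 43.5 ± 12.6 and Inhba at 232 ± 186 and 79.3 ± 36.1. Without CTX_HCQ 3 the median of this list was 0.005 (adjusted p 0.546), and the CTX_HCQ libraries stood at -0.1, -0.01 and 0.34 on it. Endothelial markers were higher in 10 of 11 (median 0.26, adjusted p 0.042, estimated-correlation adjusted p 0.843, median 0.574 without Control 1, 0.098 without Control 2, 0.13 without Control 3 and 0.397 without CTX_HCQ 1), with Plvap at 6.94 ± 5.57 and 3.16 ± 0.684. Without CTX_HCQ 2 the median of this list was -0.115 (adjusted p 0.808). With an estimated correlation none of the 9 was called, and fry called 0. The calls of the lysosome and erythroid lists held with each of the 9 libraries left out, though not every library followed them. On the lysosome list CTX_HCQ 1 stood at 0.12, beside 0.15, 0.11 and 0.13 in Control, and the other CTX_HCQ libraries at -0.15 and -0.32. On the erythroid list CTX_HCQ 2 stood at 0.65, above Control 1 at -0.29 and Control 2 at 0.48, while Control 3 held 2.48. For CTX_HCQ against CTX the lysosome list was not called by camera (median -0.079, adjusted p 0.312). Of 18 alternatives, 1 called it there, the omission of CTX_HCQ 1, and its median ran from -0.18 to 0.032 over them. Other calls ended when 1 library was left out, with adjusted p from 0.0543 to 0.808. Those of the granulosa, ovulation, endothelial and p53 lists ended without Control 2 and without Control 3. Without Control 2 the lymphocyte and cell cycle lists were not called either. The granulosa, ovulation, p53 and cell cycle lists were not called without CTX_HCQ 3, nor the ovulation, endothelial and p53 lists without CTX_HCQ 2. The lymphocyte and cell cycle lists were not called without CTX_HCQ 1, nor the endothelial list without CTX 2. Among these 9 omissions, senescence effectors were called only without Control 2 and without CTX 1. With a mean FPKM of at least 5 the p53 list was not called and the lymphocyte list held too few genes, with quantile normalization or recovered totals the endothelial and cell cycle lists, and with the length trend removed the cell cycle list. The senescence list was not called in these settings other than recovered totals, nor with a pseudocount of 0.1. With the ovulation list as covariate the granulosa, ovulation, endothelial, p53 and cell cycle lists were not called, and 6 others were, namely oocyte, adipocyte, interferon-stimulated, mitochondrially encoded, cholesterol synthesis and matrix genes. Adjusted p of the lost lists in these settings ran from 0.0528 to 0.956. With 1 library left out, 7 lists were gained without CTX_HCQ 2 and 4 each without Control 2 and without Control 3. Without CTX 3 and CTX_HCQ 3 together 3 of the 9 lists were still called, namely lysosome, erythroid and lymphocyte genes (adjusted p 0.0271, 0.0376 and 0.0201), and 6 were not. The 2 lists called there in addition were nuclear oxidative phosphorylation (median 0.361, adjusted p 6.33e-08) and immediate early genes (median 0.346, adjusted p 0.00719), both higher in CTX_HCQ.

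Of the 29 lists, 13 were called in no comparison when all 9 libraries were used. The list of the cGAS-STING pathway was higher in CTX than Control in 8 of 11 members with a median of 0.02 (adjusted p 0.471), and its median was 0.04 for CTX_HCQ against CTX (adjusted p 0.907). The senescence-associated secretory list, of which 8 of 21 genes were measured, had medians of -0.03 and -0.01 in these 2 comparisons (adjusted p 0.971 and 0.76). In the third, Ccl5 was the 1 gene that passed when adjusted over the list alone. Genes of mitochondrial DNA upkeep, dynamics and mitophagy had medians of -0.04 and -0.06 (adjusted p 0.971 and 0.824), core apoptosis genes 0 and -0.03 (adjusted p 0.971 and 0.944), and unfolded protein response genes 0.17 and -0.06 (adjusted p 0.225 and 0.453). Among markers of other cells, the medians in CTX against Control were 0.14 for luteal and steroidogenic cells, 0.08 for theca, -0.31 for fibroblasts and stroma, 0.47 for smooth muscle and pericytes, 0.13 for macrophages, 0.07 for oocytes, 0.01 for surface and oviduct epithelium and -0.01 for adipocytes, with adjusted p between 0.113 and 0.853. In the epithelial list Ovgp1 and Foxj1 were the 2 genes that passed when adjusted over the list alone, in both CTX against Control and CTX_HCQ against CTX. For the secretory, mitophagy and adipocyte lists the direction of the test in CTX against Control was up, against the sign of the median.

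Whether the values under both drugs opposed those under cyclophosphamide was measured across genes. The log2 differences of CTX minus Control and CTX_HCQ minus CTX correlated at r = -0.734 over 14431 genes, and 75.7% of genes had opposite signs. Both differences contain the CTX libraries, and unchanged groups gave a mean of -0.486, with 95% of simulated values between -0.805 and -0.00917, a range that holds the observed value. The covariance was -0.112, and -0.0532 was simulated for unchanged groups. Against CTX_HCQ minus Control, the correlation of CTX minus Control was 0.498, where unchanged groups gave 0.479 on average and 95% of values between 0.0073 and 0.802. With 0 genes called in each comparison, calls had no overlap to count. The 3 shared libraries could not be split into 2 sets of at least 2, and part of these correlations may come from them. Genes are not independent replicates in these correlations.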

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

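All 3 gene counts stayed at 0 under 13 of the 14 alternatives other than leaving out 1 library, voom on recovered reads among them. Library weights were the exception, with 648 genes for CTX against Control, 1 for CTX_HCQ against CTX and 1 for CTX_HCQ against Control. The weights ran from 0.26 for CTX_HCQ 3 to 3.72 for Control 2, with 0.59 for Control 1. Other splits of the same 6 libraries gave up to 2068, 256 and 2390 genes under such weights. Leaving out 1 library gave 0 to 13, 0 to 10 and 0 to 0 genes. The counts of 13 and 10 arose without Control 1. For CTX_HCQ against CTX, Control 1 is in neither group, so the fold changes stayed the same. The 10 calls there came from the changed estimate of the spread, which the 3 groups share. For the 13 genes the cause was not tested. Called lists numbered 7 to 13 for CTX against Control (7 without CTX 2), 4 to 10 for CTX_HCQ against CTX (9 without CTX 1, 8 without CTX 3, 10 without CTX_HCQ 2) and 6 to 12 for CTX_HCQ against Control. The estimated correlation and fry each gave 0, 0 and 0 lists. Without CTX 3 and CTX_HCQ 3 together, 5 lists were called for CTX_HCQ against Control, 3 of the original 9 and 2 others, from fewer libraries. The correlation of CTX minus Control with CTX_HCQ minus CTX lay between -0.814 and -0.485 with 1 library left out and between -0.75 and -0.655 otherwise, with rotation p from 0.0685 to 0.836. Medians of some lists changed sign. With 1 library left out, nuclear oxidative phosphorylation lay between -0.699 and 0.04 (0.04 without CTX_HCQ 3) for CTX_HCQ against CTX and between -0.36 and 0.361 (0.361 without CTX_HCQ 3, and also without CTX 3 and CTX_HCQ 3) for CTX_HCQ against Control. For the latter, endothelial markers lay between -0.115 and 0.574 and immediate early genes between -0.271 and 0.346, both lowest without CTX_HCQ 2. The epithelial list lay between -0.154 (without CTX 1) and 0.107 for CTX_HCQ against CTX. With the ovulation list as covariate its own median was 0.027 for CTX against Control, as its construction implies. Of 1554 list values under alternatives, 1257 kept their direction and side of the threshold, 150 kept the side with a median of the other sign or of 0, and 147 crossed the threshold. Named genes changed sign in 50 of 3821 values, and 32 passed the threshold, all with library weights. With the replicate number as a block, 0, 0 and 0 genes and 12, 6 and 9 lists were called, senescence effectors and cell cycle genes no longer for CTX_HCQ against Control (adjusted p 0.0591 and 0.0609), and the correlation stayed at -0.734. Interferon-stimulated and matrix genes were gained there for CTX_HCQ against Control, and immediate early genes for CTX_HCQ against CTX. Deviations of same-numbered libraries correlated between -0.457 and 0.135, so the numbers gave no hint of pairing. Depth limits the short noncoding genes and Cdkn2a, which rest on few reads.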

Other observations

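The tests of a sample exchange and of oviduct tissue, the tests of the oxidative phosphorylation and antioxidant lists alone, the resampling of the second hormone list, the 2 added lists and the alternatives without CTX 3 and CTX_HCQ 3 or with the length trend removed were chosen after the results had been seen. A list of 33 motile cilia genes, written after Rsph1 and Rsph9 had been seen among the genes with the smallest p, was measured in 26 members, none of which another list holds. Its median was 0.93 higher in CTX than in Control on the log2 scale, with 26 of 26 members higher, and its median for CTX_HCQ against CTX was -1.16, with 25 of 26 lower. These counts describe the pattern and do not test it. The list was prompted by these same data, and a gene near 0 in most libraries passes the filter only through the libraries where it is high. Library medians were 0.52, -0.63 and -0.64 in Control, 0.61, 0.45 and 1.1 in CTX, and -0.47, -0.6 and -0.36 in CTX_HCQ. Foxj1, the master transcription factor of motile cilia, held 11.7, 0.425 and 0.0231 FPKM in Control, 10.6, 14 and 21.5 in CTX, and 1.56, 0.262 and 1.94 in CTX_HCQ.

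Oviduct tissue carried over at dissection may account for the cilia genes. The 4 libraries highest on the cilia list were the 4 highest in Ovgp1, an abundant transcript of the oviduct, and 1 of these 4 is Control 1. The libraries fall into separate clusters on both measures, so no correlation was computed. Ovgp1 is 1 marker, and the surface and oviduct epithelium list that holds it did not follow these 4 libraries. That list stood at 0.05 in Control 1, -0.17 in CTX 1, -0.02 in CTX 2 and 0.4 in CTX 3, against 0.24 in Control 3 and 0.06 in CTX_HCQ 1. For CTX against Control, 6 of its members were higher and 5 lower. It also holds genes of the surface epithelium, so it does not decide on oviduct tissue. A different amount of carried-over tissue in each group by chance, and an effect of the drugs on ciliated cells, both stay open.

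Cdkn1a, Adamts1, Runx1 and Edn2 were high in the same libraries, Control 2, Control 3 and CTX_HCQ 1, with Cdkn1a at 30.4, 40.7 and 25.1 FPKM and at most 8.53 elsewhere. In these libraries Cyp17a1, the androgen-forming enzyme of theca cells, stood at 0.584, 0.986 and 0.958 FPKM, and at 7.06 or more in the rest. In the ovulation list these 3 libraries lay 1.7 above the next highest, from 5 measured genes of 14 listed. Its members Ptgs2 and Pgr lay below the filter, on at most 28 and 41 reads per library. In Control 2, Control 3 and CTX_HCQ 1, Ptgs2 stood at 0.17, 0.225 and 0.369 FPKM, and at 0.213 or less in the rest. Pgr stood at 0.0196, 0.0781 and 0.0706, and at 0.145 or more in the rest. A response to luteinizing hormone before ovulation cannot be told apart from other causes. The prediction, written before, was that the same 3 libraries would be highest on a second list of such response genes. On that list of 13 measured genes, 2 of them shared with other lists, 2 of the 3 highest libraries were shared. The same held in all 13 versions with 1 gene left out. CTX_HCQ 1 stood in place 6 of 9 at -0.11 with 10 members below their mean. The prediction was thus not met. In 10000 resamples of the members, a choice made afterwards, all 3 libraries were shared in 2.46%. But the library medians ran only from -0.28 to 0.2, and the 3 highest of this list itself recurred in 10.5% of the resamples. The list therefore orders the libraries too loosely to decide. An exchange of Control 1 and CTX_HCQ 1 cannot be told apart either, since CTX_HCQ 2 and CTX_HCQ 3 correlated at 0.881 with each other and each of the other 7 libraries correlated more closely with them on average. CTX_HCQ 1 correlated at 0.981 and 0.98 with Control 2 and Control 3, and at 0.93 and 0.919 with CTX_HCQ 2 and CTX_HCQ 3. Control 1 went the other way, at 0.952 and 0.947 with Control 2 and Control 3, and at 0.942 and 0.921 with CTX_HCQ 2 and CTX_HCQ 3.

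Of the 5 lists lower in CTX_HCQ than in CTX, 3 were still called without CTX 3 and CTX_HCQ 3. The preset test also makes calls between unchanged groups, so a call that persists is weak support. The medians did not shrink for cholesterol synthesis genes (-0.915 without the 2 libraries and -0.711 with them) and interferon-stimulated genes (-0.229 and -0.211). For these genes that argues against the 2 libraries as the whole cause of the lower medians. For mitochondrially encoded genes, also still called, the median was -0.55 without these libraries and -0.984 with them, so part of that difference may rest on them. The antioxidant list (median -0.184 without them and -0.419 with them, adjusted p 0.072 without them) and the nuclear oxidative phosphorylation list (-0.003 and -0.346, adjusted p 0.737) were no longer called at these smaller medians and from fewer libraries, so their differences may rest on these libraries. Length-dependent loss of RNA in CTX_HCQ 3 was tested by removing a trend on gene length. The median of the oxidative phosphorylation list in CTX_HCQ 3 moved from -0.93 to -0.6, still below the -0.15 of the next library. The lengths were summed over all annotated exons of a gene and can exceed those of its transcripts. A loss that depends on transcript length may thus be removed only in part, and the test cannot decide whether length is the whole cause. An effect of hydroxychloroquine stays open, with 0 genes called by limma (785 at an unadjusted p under 0.05, 748 with voom) and 0 lists with an estimated correlation in this comparison, and all 5 calls come from the preset test.

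The 6 libraries of each comparison can be grouped in 10 ways, the real split included, too few for a share under 0.05. The real split called 0 genes for CTX against Control and the highest other 0. For CTX_HCQ against CTX the real split called 0 and the highest other 57, and for CTX_HCQ against Control 0 and 272. Any split reaches a count of 0, so these counts say nothing of the grouping by treatment. At an unadjusted p under 0.05 the real and highest other counts were 1126 and 1050 for CTX against Control, 785 and 3204 for CTX_HCQ against CTX, and 312 and 1755 for CTX_HCQ against Control, with 0, 6 and 7 of the 9 other splits above the real one. The split with 272 genes set Control 1, CTX_HCQ 2 and CTX_HCQ 3 against Control 2, Control 3 and CTX_HCQ 1, which points to a structure of the libraries other than their labelled groups. This split is also the labelling with Control 1 and CTX_HCQ 1 exchanged, and it does not tell an exchange from other causes. For gene lists, the real and highest other counts were 12 and 13 for CTX against Control, 5 and 11 for CTX_HCQ against CTX, and 9 and 12 for CTX_HCQ against Control, with 2, 9 and 5 of the 10 splits, the real one included, reaching the real count.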
